A study of Arabidopsis thaliana with 42 samples.

How the data were processed

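The series holds 42 samples of Arabidopsis thaliana seedlings, 12 of RNA-seq and 30 of ChIP-seq, and the ChIP-seq samples are not analysed here. The RNA-seq libraries come from total RNA of seedlings 14 days old, harvested per the labels at ZT-6. They form 6 groups of 2: Col-0 wild type at 22 and 27 °C, vil1 (vil1-1 in the titles) at 22 and 27 °C, arp6 at 22 °C and arp6vil1 at 22 °C. The labels mention long and short days without saying which was used for RNA. Per the submitters' processing notes, reads were handled with FastQC, HISAT2, Bowtie2, SAMtools, bedtools and edgeR on TAIR10, and the notes as given here do not tie each tool to a data type. The authors deposited 1 table of RPKM (reads per kilobase of gene, scaled to depth) for 34262 features and all 12 libraries, already scaled to each library's depth.

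Of the features, 32833 have an Arabidopsis locus ID and 1429 are Ensembl noncoding RNA IDs. A reference gene table matched 32548 loci and gave a symbol to 10804. Values of 1392 features are identical to those of another feature, and 1430 lie within 1 percent of another, so their identity is uncertain. 76 features are at 0 in every library. Depth was worked out from the table itself: for each library, the read total was found that turns every RPKM, with the feature's length, into whole reads. That recovered 32520 of 32536 features with a length (tolerance 0.02 reads), and 99.94 to 99.95 percent of values became whole. Depths were 52.5 to 102.8 M reads per library.

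The main test fitted log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, 1 mean per group over all 12 libraries, with empirical Bayes variances that follow the mean level. It used the 31454 features at RPKM 1 or more in at least 2 libraries, and the Benjamini-Hochberg adjusted p had to be under 0.05 with no minimum change. The contrasts were 27 against 22 °C in WT and in vil1, the difference of these 2 responses, vil1 against WT at each temperature, arp6 against WT, arp6vil1 against arp6, WT and vil1 at 22 °C, and the difference of the ARP6 effect between vil1 and WT plants. Each group has 2 libraries, so no permutation of the labels reaches a small p, and none was run.

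The 23 gene lists, with 412 genes, cover warm-response markers, auxin synthesis and response, SAUR genes, heat shock and protein folding, flowering time, Polycomb components and H3K27 demethylases, the SWR1 complex and H2A.Z, Polycomb-silenced developmental regulators, light signalling, the circadian clock, gibberellin and brassinosteroid, cell-wall expansins and xyloglucan enzymes, salicylic acid defence, jasmonate and ethylene defence, cold and abscisic acid response, flavonoid and anthocyanin, photosynthetic antenna and Rubisco, glucosinolate synthesis, senescence and sugar starvation, iron and phosphate starvation, and markers of root cells, dividing cells and seed storage. They were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and the rotation test fry beside it. List medians are given after the median of all genes is subtracted. Where a list's median after that step, its mean and its test differ in sign, the text gives them.

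Before the data were examined, the groups, contrasts, tests, lists, named-gene rule and most alternatives were fixed. The rule names VRN5 and ARP6 first, then the 8 largest rises and falls (4 in the smaller comparisons) among genes past the threshold with a symbol, separated libraries and a mean RPKM of 5 or more in a group, then up to 4 members of each list, and FLC, FT, PIF4, YUC8, IAA19, IAA29, HSP70-4 (written HSP70) and HB-2 wherever their lists are discussed. Genes listed at 0 in a whole group are given no fold change.

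Genes suppressed or induced at 27 °C in WT were chosen from 1 library of each WT group and measured in the others, in all 4 ways, so that choice and measurement share no library. The chosen genes have RPKM 5 or more and a log2 change of 1 or more. The same was done for genes changed in arp6. Likeness between 2 sets of changes is the Pearson correlation and covariance over all tested genes, set beside 100 simulations without change that share the WT 22 °C libraries as the data do.

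The alternatives set before the data were examined were a pseudocount of 0.1 or 5, no filter or mean RPKM of 5 or more, quantile normalization, median centring, no variance trend, only the groups of the contrast, the replicate number as a block, a minimum absolute log2 change of 1, and leaving out each library in turn. Chosen after seeing the data were a mean RPKM of 10 or more and subtraction of each library's background (10th percentile of nuclear coding genes). So were removal of a gene length trend (lowess, span 0.3), nuclear protein-coding genes alone (27432) and WT and vil1 libraries alone. The rest were limma's voom on recovered reads (29859 genes), median centring for lists, and combinations of these. Length trends were fitted at mean RPKM 10 or more and applied to 29875 tested genes with a length. They were read in 5 equal bins of 6996 nuclear coding genes at that level.

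The steps were tested on simulated data with 200 changed genes in 10 draws. For WT at 27 against 22 °C, limma recovered 93.5 and 99.6 percent of log2 changes of 1 and 2 with a mean of 12.5 false calls. For the difference between vil1 and WT, these were 77.8 and 98.6 percent with 11.1. Adding a length trend gave a mean of 4873 false calls, and 12.1 after its removal. WT 22 °C replicates differ along length, so these rates need not hold here. The held-out reading returned 49.9 percent for a true 50 percent. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.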

Results

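RNA sequencing of whole Arabidopsis seedlings, 14 days old, gave 12 libraries in 6 groups of 2. Wild type (WT) and vil1 plants were grown at 22 and 27 °C, and arp6 and arp6vil1 plants at 22 °C. VIL1 (gene symbol VRN5) is a PHD-finger protein that acts with Polycomb repressive complex 2, which places the H3K27me3 mark. ARP6 is a subunit of the SWR1 complex, which deposits the histone variant H2A.Z. Levels below are in RPKM, and the value after ± is the SD over 2 libraries. Changes are log2, with the SE of a model fitted to all 12 libraries. Rises and falls in a gene list adjusted over the list alone are given in brackets where they differ from those adjusted over all genes. A p marked estimated is camera's adjusted p with an estimated correlation. Every p-value measures only the spread between these libraries, since nothing in the labels says that the 2 of a group are separate cultures of plants.

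Depths in replicates 1 and 2, in M reads, were 75 and 61.6 for WT at 22 °C, 75 and 61.5 for WT at 27 °C, 73.5 and 86.9 for vil1 at 22 °C, and 81.0 and 58.6 for vil1 at 27 °C. They were 54.6 and 52.5 for arp6 and 86.3 and 102.8 for arp6vil1. The arp6 and arp6vil1 libraries stand apart from the rest. In arp6, 6651 and 6566 features are listed at 0, against 104 to 194 in the other libraries. The median transfer RNA gene is at 0 there, against 0.662 to 1.8 elsewhere. In arp6vil1, an 18S ribosomal RNA gene has 40305 and 35544 RPKM, against 2300.3 to 4510 elsewhere. Chloroplast genes hold 17 and 14.9 percent of its summed RPKM, against 4.07 to 7.64 percent, and its median coding gene has 1.94 and 1.79 RPKM, against 3.34 to 4.97. Pearson r was 0.9804 to 0.9936 within the 6 pairs of replicates, 0.9511 to 0.9858 between groups of WT and vil1, and 0.7983 to 0.8015 between arp6 and arp6vil1.

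ARP6 RNA was nearly absent from arp6 and arp6vil1 plants, while VRN5 RNA in vil1 lay near its WT level. ARP6 was at 14 ± 0.557 RPKM in WT at 22 °C, 12.8 ± 0.943 in WT at 27 °C, 14.2 ± 0.238 in vil1 at 22 °C and 13.1 ± 1.43 in vil1 at 27 °C. It fell to 0.303 ± 0.135 in arp6 (log2 change -3.53, SE 0.11, adjusted p = 1.17e-08) and to 0.756 ± 0.0584 in arp6vil1 (-3.10, SE 0.11, adjusted p = 8.5e-08). VRN5 was at 6.69 ± 0.0221 in WT and 5.26 ± 0.178 in vil1 at 22 °C, 8.5 ± 0.298 and 6.59 ± 0.452 at 27 °C, 8.4 ± 0.411 in arp6 and 2.49 ± 0.00144 in arp6vil1. It did not pass in vil1 against WT at 22 °C (-0.30, SE 0.08, adjusted p = 0.0669) or 27 °C (-0.32, SE 0.08, adjusted p = 0.13), and fell in arp6vil1 against WT (-1.14, SE 0.08, adjusted p = 1.86e-06). VRN5 does pass at 22 °C among genes at mean RPKM 5 or more (adjusted p = 0.0388), or once a trend with gene length is removed (adjusted p = 0.0262). Its level therefore does not check the vil1 genotype, which rests on the labels (vil1-1 in the titles).

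In WT plants at 27 °C, heat-shock protein genes rose. HSP17.4, a small heat-shock protein, rose from 3.42 ± 0.777 to 60.6 ± 27.7 RPKM (log2 change 3.74, SE 0.25, adjusted p = 0.000138). Its mitochondrial relative HSP23.6-MITO rose from 11.2 ± 3.47 to 103 ± 51.6 (3.02, SE 0.31, adjusted p = 0.000524), and the chaperone gene HSP70 from 20.06 ± 7.4 to 122 ± 1.27 (2.60, SE 0.21, adjusted p = 0.000229). HSP90.1 (2.28, SE 0.20, adjusted p = 0.000276), the chloroplast HSP90 gene CR88 (2.099, SE 0.26, adjusted p = 0.00113) and the small heat-shock gene AT1G53540 (2.68, SE 0.21, adjusted p = 0.000185) rose as well. Of 32 heat shock and protein folding genes, 25 rose, 1 fell and 6 did not pass. The list's median lay 0.85 above that of all genes (camera adjusted p = 2.59e-12, estimated 0.0943). Other large rises were AIR1, an auxin-induced root gene (3.33, SE 0.28, adjusted p = 0.000271), and the defensin-like gene LCR85 (2.63, SE 0.32, adjusted p = 0.00114). The β-glucosidase BGLU18 (2.60, SE 0.22, adjusted p = 0.000271) and VSP1, a vegetative storage protein (2.01, SE 0.21, adjusted p = 0.000592), rose too. Of the RADIALIS-like MYB genes, MEE3 fell from 14.2 ± 0.238 to 3.12 ± 0.206 RPKM (-1.89, SE 0.15, adjusted p = 0.000229). RL4 (-1.64, SE 0.12, adjusted p = 0.000164) and RL6 (-1.44, SE 0.14, adjusted p = 0.000464) fell with it. The spliceosomal RNA U4.11p (-1.72, SE 0.17, adjusted p = 0.000499), SCRL22 (-1.68, SE 0.14, adjusted p = 0.000237) and the thionin THI2.2 (-1.58, SE 0.20, adjusted p = 0.00127) were lower as well. PCC1, a pathogen- and clock-controlled gene, fell by 1.78 (SE 0.38, adjusted p = 0.00991). That call is lost without WT 22 °C replicate 2 (adjusted p = 0.0617) or WT 27 °C replicate 1 (adjusted p = 0.0788). MIR841b fell too (-1.58, SE 0.17, adjusted p = 0.000652), but its values are nearly those of another locus, so which of them changed is uncertain.

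**Figure D1:**
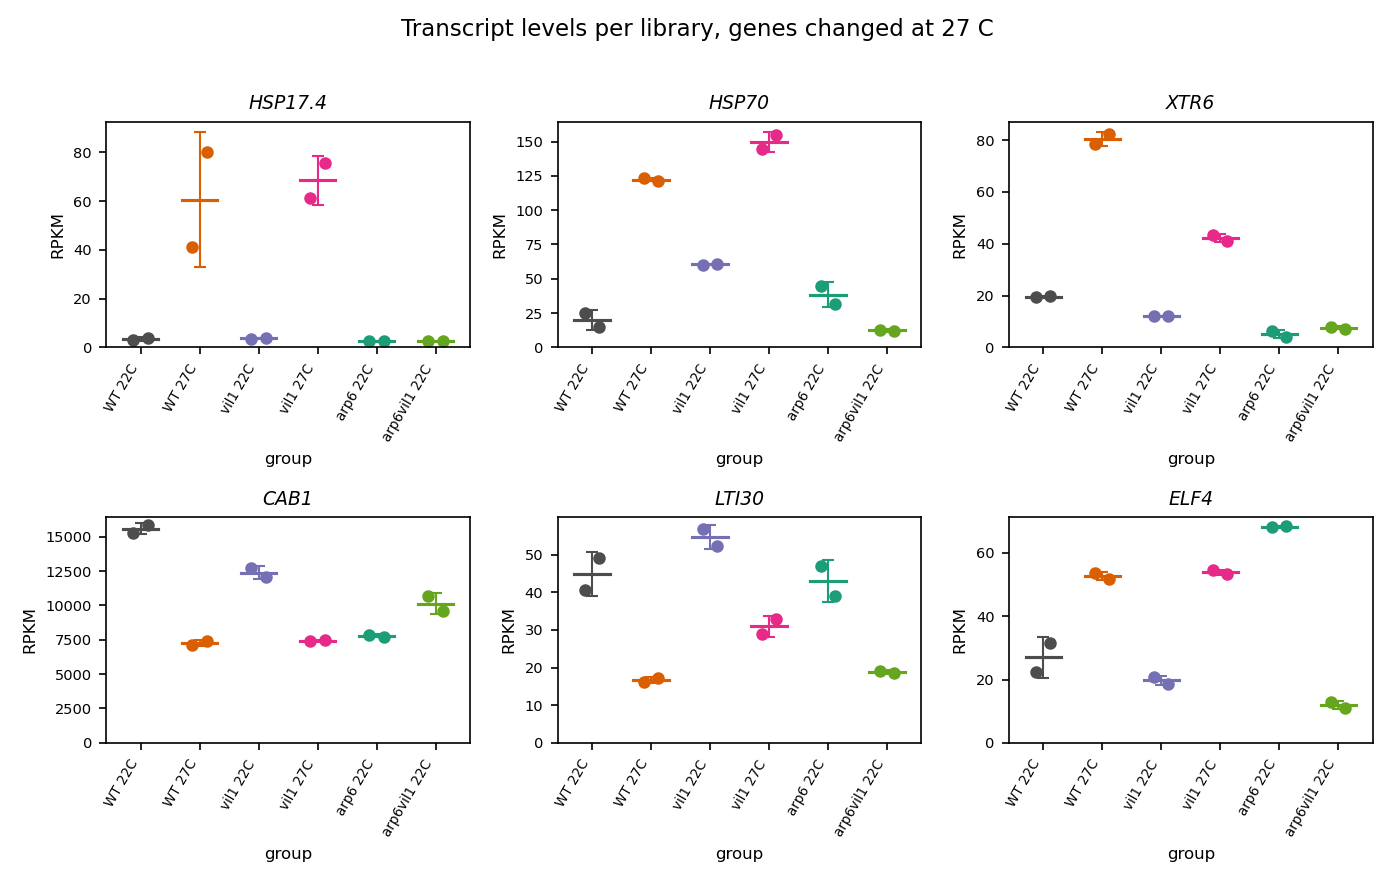
Levels of 6 warm-regulated genes in each library (points, RPKM on a linear axis), with group means (lines) and SDs (bars), 2 libraries per group. HSP17.4 averages 3.42 and 60.6 RPKM in WT at 22 and 27 °C, and CAB1 15571 and 7284.

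Antenna, SAUR, flowering-time and cold response lists lay lower in warm WT plants, each median given relative to all genes. Of 18 photosynthetic antenna and Rubisco genes, 0 rose, 13 fell and 5 did not pass (0 and 14 adjusted over the list alone). They lay lower (median -0.66, camera adjusted p = 2.93e-16, estimated 0.149). CAB1, a chlorophyll-binding protein, went from 15571 ± 413 to 7284 ± 222 RPKM (-1.10, SE 0.11, adjusted p = 0.000579). Quantile normalization ends both the list's call (adjusted p = 0.619) and that of CAB1 (-0.34, adjusted p = 0.0959). Of 18 SAUR genes, a family of auxin-responsive growth genes, 0 rose, 10 fell and 8 did not pass (0 and 12 adjusted over the list alone). SAUR genes lay lower (median -0.57, camera adjusted p = 7.44e-12, estimated 0.211), SAUR68 among them (-0.80, SE 0.12, adjusted p = 0.00301). Of 22 flowering-time genes, 2 rose, 5 fell and 15 did not pass. That list lay lower (median -0.15, camera adjusted p = 0.00155, estimated 0.472), but not at mean RPKM 10 or more (adjusted p = 0.0616) or by fry (0.192). RAV2 (-0.88, SE 0.12, adjusted p = 0.00173) and TEM1 (-0.79, SE 0.14, adjusted p = 0.00504), repressors of FT, fell, as did AGL20, which promotes flowering (-0.83, SE 0.11, adjusted p = 0.00128). Of 17 cold and abscisic acid response genes, 3 rose, 6 fell and 8 did not pass. Theirs was the next lower median (median -0.18, camera adjusted p = 0.00155, estimated 0.144), with the dehydrin LTI30 (-1.37, SE 0.12, adjusted p = 0.000289) and KIN1 (-1.08, SE 0.16, adjusted p = 0.00228). The cold call is lost without WT 22 °C replicate 1 (adjusted p = 0.0585) or with the length trend removed (adjusted p = 0.24).

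Clock, light and pigment genes moved higher. Of 23 circadian clock genes, 14 rose, 0 fell and 9 did not pass (16 and 0 adjusted over the list alone). The clock list (median 0.44, camera adjusted p = 0.000313, estimated 0.144) included ELF4, an evening-complex gene (0.96, SE 0.14, adjusted p = 0.00225), and COR27 (0.89, SE 0.18, adjusted p = 0.00813). Of 20 flavonoid and anthocyanin genes, 10 rose, 0 fell and 10 did not pass. This list (median 0.44, camera adjusted p = 0.00305, estimated 0.561) loses its call without WT 22 °C replicate 1 (adjusted p = 0.0517). In it the MYB activator PAP1 (1.09, SE 0.18, adjusted p = 0.00396) and chalcone synthase TT4 (0.98, SE 0.19, adjusted p = 0.00747) rose. Of 20 light signalling genes, 10 rose, 0 fell and 10 did not pass (11 and 0 adjusted over the list alone). The light list (median 0.28, camera adjusted p = 0.00155, estimated 0.374) included the photoreceptor PHYB (0.70, SE 0.12, adjusted p = 0.00502), and loses its call without WT 22 °C replicate 2 (adjusted p = 0.102). Of 14 glucosinolate synthesis genes, 6 rose, 0 fell and 8 did not pass (8 and 0 adjusted over the list alone). SOT16 (1.06, SE 0.16, adjusted p = 0.00259) and CYP83A1 (0.86, SE 0.13, adjusted p = 0.00237) rose among them (median 0.26, camera adjusted p = 0.00534, estimated 0.374). Of 22 Polycomb components and H3K27 demethylases, 6 rose, 0 fell and 16 did not pass (8 and 0 adjusted over the list alone). VEL1, a relative of VIL1, rose (0.80, SE 0.13, adjusted p = 0.00428), and the list lay higher (median 0.14, camera adjusted p = 0.00565, estimated 0.472). Of 8 dividing cell markers, 3 rose, 0 fell and 5 did not pass (4 and 0 adjusted over the list alone). These markers lay higher (median 0.14, camera adjusted p = 0.04, estimated 0.472), with the cytokinesis syntaxin SYP111 (1.01, SE 0.12, adjusted p = 0.000888). Their call is lost without WT 22 °C replicate 1 (adjusted p = 0.108) or 2 (0.0524), WT 27 °C replicate 1 (0.0641), or arp6vil1 replicate 1 (0.0501) or 2 (0.0503). Clock, light, Polycomb, glucosinolate and dividing cell calls end once the length trend is removed (adjusted p = 0.111, 0.395, 0.0809, 0.0511 and 0.111, the Polycomb median turning to -0.24). Quantile normalization ends the Polycomb and dividing cell calls too (adjusted p = 0.0719 and 0.0935), and mean RPKM 10 or more the light and glucosinolate calls (0.0952 and 0.11). With the length trend removed PHYB does not pass either (0.14, adjusted p = 0.477).

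Warm-response markers did not move as a list. Of 17 such markers, 3 rose, 2 fell and 12 did not pass (4 and 3 adjusted over the list alone). Relative to all genes they lay at -0.12 (camera adjusted p = 0.154, estimated 0.472), with a mean of 0.06 against a median of -0.04 before that step. Without WT 22 °C replicate 2 the list passes, lower (adjusted p = 0.0181). YUC8, an auxin synthesis enzyme, rose by 0.36 (SE 0.10, adjusted p = 0.0266). This ends without WT 22 °C replicate 1 (adjusted p = 0.0906) or 2 (0.0526) or WT 27 °C replicate 1 (0.161), and with quantile normalization (0.301), median centring (0.229) or the length trend removed (0.0678). IAA29 fell (-0.69, SE 0.13, adjusted p = 0.00643), but not without WT 27 °C replicate 1 (adjusted p = 0.0502). The thermomorphogenesis regulator PIF4 (0.05, SE 0.14, adjusted p = 0.889) and its targets IAA19 (-0.18, SE 0.12, adjusted p = 0.353) and HB-2 (0.25, SE 0.11, adjusted p = 0.143) did not pass. Nor did the flowering repressor FLC (-0.02, SE 0.10, adjusted p = 0.918), except with the length trend removed (-0.72, adjusted p = 0.0352). Without WT 22 °C replicate 1, PIF4 and HB-2 pass, higher (adjusted p = 0.0444 and 0.0313). PIF4 passes lower with the length trend removed at mean RPKM 10 or more (-0.28, adjusted p = 0.031) or after background subtraction (-0.30, adjusted p = 0.0397). IAA19 passes lower with quantile normalization (-0.37, adjusted p = 0.0346) or median centring (adjusted p = 0.0348). FT, the flowering inducer, was not tested, since every library has under 1 RPKM.

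Of 30 auxin synthesis and response genes, 2 rose, 6 fell and 22 did not pass (2 and 7 adjusted over the list alone). The auxin list lay lower (median -0.15, camera adjusted p = 0.0369, estimated 0.561), but not without WT 22 °C replicate 1 (adjusted p = 0.234), with another scaling (0.0817 quantile, 0.0591 median) or with the length trend removed (0.0511). Of 21 gibberellin and brassinosteroid genes, 2 rose, 2 fell and 17 did not pass (2 and 1 adjusted over the list alone). As a list they did not pass (median -0.05, camera adjusted p = 0.171, estimated 0.821), with a mean of -0.01 and a median of 0.03 before that step. Of 21 cell-wall expansins and xyloglucan enzymes, 7 rose, 4 fell and 10 did not pass (8 and 8 adjusted over the list alone). They did not pass together (median 0.11, camera adjusted p = 0.889, estimated 0.944), though XTH18 (2.08, SE 0.14, adjusted p = 0.000138) and XTR6 (1.99, SE 0.13, adjusted p = 0.000138) rose. The expansin EXPA11 fell (-1.03, SE 0.15, adjusted p = 0.00204). Of 11 iron and phosphate starvation genes, 5 rose, 2 fell and 4 did not pass. This list did not pass (median 0.12, camera adjusted p = 0.806, estimated 0.88). BHLH100 (1.72, SE 0.31, adjusted p = 0.00512) and bHLH39 (1.33, SE 0.21, adjusted p = 0.0032), which act in iron uptake, rose, and the ferritin FER1 fell (-1.22, SE 0.11, adjusted p = 0.000398).

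In all, 6465 of 31454 genes passed in warm WT plants (limma, adjusted p under 0.05), 5328 higher and 1137 lower, and the median of all genes was 0.09. The split follows scaling and gene length: 2055 higher and 2528 lower with quantile normalization, 1186 and 3160 with median centring, and 2117 and 1998 with the length trend removed. Change rose with length at a Spearman rho of 0.493, and the 2 WT 22 °C libraries, replicate 1 against 2, differed along length at 0.567. The count is 2047 without WT 27 °C replicate 1 and 3469 without WT 22 °C replicate 2. It is 1290 when the 2 WT groups are fitted alone.

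In vil1 plants, heat-shock and anthocyanin genes rose at 27 °C. HSP17.4 went from 3.66 ± 0.343 to 68.5 ± 10.1 RPKM (log2 change 3.89, SE 0.25, adjusted p = 8.44e-05), and AT1G53540 from 4.37 ± 0.401 to 56.7 ± 3.36 (3.42, SE 0.21, adjusted p = 7e-05). The anthocyanin enzyme DFR went from 6.88 ± 1.96 to 49.9 ± 0.951 (2.71, SE 0.30, adjusted p = 0.00153) and LDOX from 7.25 ± 1.12 to 51.4 ± 1.96 (2.67, SE 0.20, adjusted p = 0.000218). UF3GT (2.45, SE 0.21, adjusted p = 0.000378), AT5MAT (2.17, SE 0.23, adjusted p = 0.00131) and GSTF12 (2.14, SE 0.24, adjusted p = 0.00173) of the same pathway rose too. So did ELF4 (1.41, SE 0.14, adjusted p = 0.000834) and XTR6 (1.71, SE 0.13, adjusted p = 0.000317). MEE3 (-1.84, SE 0.15, adjusted p = 0.000356), RL4 (-1.33, SE 0.12, adjusted p = 0.000591), RL6 (-1.17, SE 0.14, adjusted p = 0.00259) and the glutathione transferase GSTU24 (-1.37, SE 0.17, adjusted p = 0.00259) fell. HSP70 rose from 60.6 ± 0.289 to 149.9 ± 7.36 (1.29, SE 0.21, adjusted p = 0.011). Its call is lost without vil1 22 °C replicate 1 (adjusted p = 0.0999) or 2 (0.0866), or vil1 27 °C replicate 1 (0.0812) or 2 (0.09).

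Of 32 heat shock and protein folding genes, 17 rose, 0 fell and 15 did not pass (24 and 0 adjusted over the list alone). Their call in vil1 holds either way (median 0.70, camera adjusted p = 3.58e-20, estimated 0.0263, all medians here relative to that of all genes, 0.11). Of 20 flavonoid and anthocyanin genes, 14 rose, 0 fell and 6 did not pass (15 and 0 adjusted over the list alone). The pigment list lay higher (median 0.96, camera adjusted p = 6.65e-18, estimated 0.184). Of 18 antenna and Rubisco genes, 0 rose, 8 fell and 10 did not pass (0 and 13 adjusted over the list alone). These lay lower (median -0.53, camera adjusted p = 2.43e-21, estimated 0.171). Of 12 senescence and sugar starvation genes, 0 rose, 0 fell and 12 did not pass. As a list they lay lower (median -0.15, camera adjusted p = 0.00395, estimated 0.257), though not without vil1 27 °C replicate 1 (adjusted p = 0.133). Of 23 circadian clock genes, 5 rose, 0 fell and 18 did not pass (7 and 0 adjusted over the list alone). The clock list lay higher (median 0.05, camera adjusted p = 0.0182, estimated 0.323), but not without vil1 22 °C replicate 1 (adjusted p = 0.0512) or vil1 27 °C replicate 2 (0.183). Senescence and clock calls also end at mean RPKM 10 or more (adjusted p = 0.393 and 0.129). Camera also passed lower medians of auxin (-0.16, adjusted p = 7.91e-05), jasmonate and ethylene (-0.13, adjusted p = 0.00334), SAUR (-0.13, adjusted p = 0.00375), flowering-time (-0.09, adjusted p = 0.00334) and gibberellin genes (-0.09, adjusted p = 0.0442), and a higher one of Polycomb components (0.05, adjusted p = 0.0277). None of these 6 passed with an estimated correlation (adjusted p = 0.323 for the lowest). In all, 755 genes passed, 610 higher and 145 lower. The split is 379 and 332 with quantile normalization, 266 and 363 with median centring, and 483 and 461 with the length trend removed. The count is 149 and 156 without vil1 22 °C replicate 1 and 2, 150 and 208 without vil1 27 °C replicate 1 and 2, and 1269 and 1271 without WT 22 °C replicate 1 and 2. It is 2088 when the 2 vil1 groups are fitted alone.

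No gene's change at 27 °C differed between vil1 and WT by the interaction test in limma, 3880 had an unadjusted p under 0.05, and voom passed 7. For HSP70 the difference was -1.302 (SE 0.29, adjusted p = 0.372), for PIF4 -0.28 (adjusted p = 0.59) and for HB-2 -0.38 (adjusted p = 0.386). SAUR (0.44, camera adjusted p = 2.09e-08), flavonoid and anthocyanin (0.42, adjusted p = 1.87e-08) and cold and abscisic acid response genes (0.24, adjusted p = 0.00236) lay higher in vil1, and light signalling (-0.29, adjusted p = 0.000345) and dividing cell genes (-0.22, adjusted p = 0.00141) lower. Each of these lists has an estimated p of 0.315, and none passes fry. Adjusted over the list alone, 8 flavonoid and 4 cold genes pass. The difference falls along gene length at a rho of -0.566, and with that trend removed the light (-0.0442, adjusted p = 0.356) and cold calls (0.12, adjusted p = 0.163) end. The cold call also ends without WT 22 °C replicate 1 (adjusted p = 0.156). Without WT 22 °C replicate 1, 1803 genes pass, 553 higher and 1250 lower, HSP70 (adjusted p = 0.0123) and PIF4 (0.0355) among them.

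Genes suppressed in warm WT plants also fell in vil1, by less. Values are medians over genes chosen from 1 library of each WT group, averaged over all 4 ways. The 52 to 256 chosen genes changed by -0.86 in the held-out WT libraries (lowest -1.203, highest -0.58) and by -0.48 in vil1 (lowest -0.78, highest -0.29), and 81.6 percent moved the same way. The 215 to 1077 warm-induced genes changed by 0.81 in held-out WT and 0.49 in vil1, with 89.6 percent moving the same way. In vil1 the fall was 55.4 percent of that in WT, and the rise 60.4 percent, with no p-value for the difference. With a smaller minimum log2 change of 0.58, suppressed genes changed by -0.57 in held-out WT and -0.25 in vil1 (44.3 percent). With genes chosen by the fit of all libraries, so not held out, the changes were -0.54 and -0.19 (34.7 percent), and 0.51 and 0.20 at induced genes (39.8 percent).

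In vil1 against WT at 22 °C, the orphan gene QQS, which acts on starch content, rose from 1.35 ± 0.292 to 17.5 ± 0.357 RPKM (log2 change 2.98, SE 0.12, adjusted p = 6.06e-06). The cold-regulated COR15B rose from 27.7 ± 3.45 to 79.1 ± 2 (1.49, SE 0.11, adjusted p = 0.000348). MRD1 fell from 34 ± 5.94 to 6.57 ± 0.588 (-2.201, SE 0.14, adjusted p = 0.000128) and its neighbour HEI10, a meiotic crossover factor, from 15.6 ± 2.7 to 3.58 ± 0.154 (-1.84, SE 0.13, adjusted p = 0.000239). These 4 calls hold without any single library. HSP70 went from 20.06 ± 7.4 to 60.6 ± 0.289 (1.59, SE 0.21, adjusted p = 0.00793), with adjusted p = 0.0703 and 0.0733 without vil1 22 °C replicate 1 and 2, and 0.0771 with these groups alone. LSU1, a sulfur-starvation gene, went from 423 ± 67.3 to 141 ± 4.5 (-1.57, SE 0.21, adjusted p = 0.00805). Its adjusted p is 0.0762 without WT 22 °C replicate 2, and 0.0703 and 0.0788 without vil1 22 °C replicate 1 and 2.

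Gene groups in vil1 at 22 °C are given relative to the median of all genes, -0.16. Of 17 cold and abscisic acid response genes, 3 rose, 0 fell and 14 did not pass (5 and 1 adjusted over the list alone). They lay higher (median 0.24, camera adjusted p = 0.0072, estimated 0.258). Of 12 senescence and sugar starvation genes, 2 rose, 0 fell and 10 did not pass (4 and 0 adjusted over the list alone). That list was higher too (median 0.31, camera adjusted p = 0.00121, estimated 0.258). Of 32 heat shock genes, 5 rose, 0 fell and 27 did not pass (7 and 4 adjusted over the list alone). The heat shock list lay higher (median 0.17, camera adjusted p = 0.0264, estimated 0.596), but not without WT 22 °C replicate 1 (adjusted p = 0.076). Of 20 light signalling genes, 1 rose, 1 fell and 18 did not pass (9 and 3 adjusted over the list alone). The light list lay higher (median 0.38, camera adjusted p = 0.000747, estimated 0.416), though not with the length trend removed (adjusted p = 0.261). Clock (0.23) and glucosinolate genes (0.14) passed camera (adjusted p = 0.0266 for both), but not with an estimated correlation (adjusted p = 0.416 and 0.596) or with the length trend removed (0.915 and 0.0596). Each of these 6 calls ends by fry (lowest adjusted p = 0.0674) and at mean RPKM 10 or more (lowest 0.0652), and quantile normalization ends the cold, heat shock and clock calls (0.106, 0.106 and 0.206). Flavonoid genes pass, lower, with the length trend removed (-0.43, adjusted p = 0.0483). PIF4 (0.44, SE 0.14, adjusted p = 0.0783) and HB-2 (0.06, SE 0.11, adjusted p = 0.727) did not pass, though PIF4 does without WT 22 °C replicate 1 (adjusted p = 0.00264), at mean RPKM 5 (0.0495) or 10 or more (0.0399), and with voom (0.0465). In all, 1291 genes passed, 677 higher and 614 lower, a count that depends on single libraries. It is 8939 without WT 22 °C replicate 1, 92 without replicate 2, 30 and 37 without vil1 22 °C replicate 1 and 2, and 494 and 490 without vil1 27 °C replicate 1 and 2. Without either arp6 library it is 546, and 503 and 504 without arp6vil1 replicate 1 and 2. The split is 860 and 364 with median centring, 1088 and 2940 with the length trend removed, and 57 genes pass when only these groups are fitted. Change rose with gene length at a rho of 0.531.

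At 27 °C, QQS rose again in vil1 against WT (log2 change 2.995, SE 0.12, adjusted p = 5.84e-06). The cold-regulated genes COR15B, from 16.6 ± 1.12 to 70.2 ± 4.28 RPKM (2.02, SE 0.11, adjusted p = 5.1e-05), and COR15A (1.73, SE 0.13, adjusted p = 0.000248) rose, as did the seed-type protein gene PAP85 (1.73, SE 0.12, adjusted p = 0.000216). AIR1 fell from 227 ± 84.1 to 36.7 ± 2.3 (-2.55, SE 0.28, adjusted p = 0.00299) and the myrosinase-binding gene MBP1 from 7.58 ± 1.26 to 0.852 ± 0.289 (-2.21, SE 0.15, adjusted p = 0.000216). XTH18 fell from 70.7 ± 9.39 to 24.6 ± 0.259 (-1.48, SE 0.14, adjusted p = 0.00104). Of 17 cold and abscisic acid response genes, 6 rose, 0 fell and 11 did not pass. Relative to all genes, whose median was -0.12, this list lay higher (median 0.27, camera adjusted p = 2.05e-12, estimated 0.0109). Of 18 SAUR genes, 0 rose, 0 fell and 18 did not pass (4 and 0 adjusted over the list alone). They lay higher as a list (median 0.38, camera adjusted p = 2.05e-12, estimated 0.315). Of 20 flavonoid genes, 2 rose, 0 fell and 18 did not pass (4 and 1 adjusted over the list alone). So did this list (median 0.30, camera adjusted p = 4.08e-08, estimated 0.369), but neither it nor SAUR passes fry (adjusted p = 0.343 and 0.225). Of 19 jasmonate and ethylene defence genes, 0 rose, 2 fell and 17 did not pass (0 and 6 adjusted over the list alone). That list lay lower (median -0.26, camera adjusted p = 0.00379, estimated 0.369), though not without WT 27 °C replicate 1 (adjusted p = 0.411) or vil1 27 °C replicate 1 (0.267). Camera also passed antenna (0.19, adjusted p = 3.77e-07), iron (0.18, adjusted p = 0.000965), gibberellin (0.11, adjusted p = 0.0396) and dividing cell genes (-0.07, adjusted p = 0.00986), none with an estimated correlation (adjusted p = 0.315 for the lowest). In all, 290 genes passed, 106 higher and 184 lower, 206 and 148 with quantile normalization, 275 and 114 with median centring. The count is 98 without WT 27 °C replicate 1, 86 and 62 without vil1 27 °C replicate 1 and 2, and 166 and 171 without vil1 22 °C replicate 1 and 2. It is 456 and 460 without WT 22 °C replicate 1 and 2, and 120 when only these groups are fitted.

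In arp6 against WT at 22 °C, the endoplasmic-reticulum chaperone gene BIP2 went from 7.31 ± 0.261 to 192 ± 16.8 RPKM (log2 change 4.53, SE 0.20, adjusted p = 7.75e-08) and BIP1 from 8.64 ± 0.0964 to 216 ± 17.5 (4.49, SE 0.21, adjusted p = 1.07e-07). The HSP90-type chaperone SHD went from 5.5 ± 0.241 to 163 ± 22.9 (4.66, SE 0.29, adjusted p = 5.87e-07), and the cold- and drought-induced LTI78 from 4.32 ± 0.771 to 112 ± 19.6 (4.41, SE 0.18, adjusted p = 4.67e-08). The starch-degrading enzyme PHS2 (3.86, SE 0.30, adjusted p = 2.03e-06), the chaperonin CPN60B (3.72, SE 0.23, adjusted p = 5.61e-07) and the defence marker PR1 (3.75, SE 0.22, adjusted p = 3.52e-07) rose too. SEX1, a long gene of starch breakdown, rose (3.90, SE 0.31, adjusted p = 2.36e-06), by 1.44 with the length trend removed. JAZ7, a jasmonate repressor, fell from 67.1 ± 7.24 to 0.431 ± 0.385 (-5.59, SE 0.18, adjusted p = 1.41e-08). ORA47 (-5.33, SE 0.11, adjusted p = 4.02e-09), OXS3 (-4.998, SE 0.21, adjusted p = 5.92e-08) and PHI-1 (-4.93, SE 0.19, adjusted p = 2.78e-08) fell, as did the xyloglucan enzymes TCH4 (-3.19, SE 0.16, adjusted p = 1.81e-07) and XTH24 (-3.06, SE 0.13, adjusted p = 7.27e-08). The microRNA loci MIR5643a and MIR5643b are listed at 0 in both arp6 libraries, against 22.5 ± 3.12 and 206 ± 55.9 RPKM in WT. MIR5642a (-4.57, SE 0.16, adjusted p = 1.69e-08) and MIR854d (-4.52, SE 0.47, adjusted p = 1.12e-05) fell. Each of these loci has nearly the values of another, so which of them changed is uncertain.

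Gene groups in arp6 are given relative to the median of all genes, which was -0.64. Salicylic acid defence (median 1.198, camera adjusted p = 3.31e-05), cold and abscisic acid response (0.79, adjusted p = 0.0392), Polycomb component (0.85, adjusted p = 0.00975), glucosinolate (0.62, adjusted p = 0.0401) and dividing cell genes (1.297, adjusted p = 0.0125) lay higher (estimated 0.6 for each). Flavonoid (0.99, adjusted p = 0.00348) and root cell genes (0.81, adjusted p = 0.0125) lay higher too (estimated 0.613 for each). Of 18 salicylic acid defence genes, 11 rose, 0 fell and 7 did not pass (10 and 0 adjusted over the list alone). BGL2 (2.31, SE 0.18, adjusted p = 2.1e-06) and PR5 (1.42, SE 0.12, adjusted p = 3.7e-06) are among them. Of 17 cold and abscisic acid response genes, 7 rose, 5 fell and 5 did not pass. Of 22 Polycomb components, 11 rose, 5 fell and 6 did not pass (10 and 5 adjusted over the list alone). Of 14 glucosinolate genes, 6 rose, 5 fell and 3 did not pass. Their median was -0.02 but their mean 0.26 before the shift, and their call ends without WT 22 °C replicate 1 (adjusted p = 0.0518) or arp6 replicate 2 (0.0541). Of 8 dividing cell markers, 5 rose, 2 fell and 1 did not pass. CDC20.1 rose (1.31, SE 0.11, adjusted p = 2.63e-06). Of 20 flavonoid and anthocyanin genes, 9 rose, 1 fell and 10 did not pass. Of 14 root cell markers, 5 rose, 3 fell and 6 did not pass (5 and 1 adjusted over the list alone). IRT1, an iron transporter, rose (2.37, SE 0.24, adjusted p = 1.06e-05), and the root call ends without WT 22 °C replicate 1 (adjusted p = 0.0506). Of 22 flowering-time genes, 2 rose, 19 fell and 1 did not pass. FLC fell from 4.61 ± 0.202 to 0.21 ± 0.032 (-2.21, SE 0.10, adjusted p = 6.82e-08), with RAV2 (-3.57, SE 0.12, adjusted p = 1.54e-08) and TEM1 (-2.81, SE 0.14, adjusted p = 1.49e-07). The flowering list lay lower (median -0.08, camera adjusted p = 0.0415, estimated 0.721), but not without WT 22 °C replicate 1 (adjusted p = 0.0506). Of 18 SAUR genes, 0 rose, 17 fell and 1 did not pass. SAUR genes lay lower (median -0.90, camera adjusted p = 0.00868, estimated 0.618). Of 18 antenna and Rubisco genes, 0 rose, 16 fell and 2 did not pass. LHCB4.2 fell (-1.82, SE 0.10, adjusted p = 2.2e-07), and the list lay lower (median -0.29, camera adjusted p = 0.0138, estimated 0.72).

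Clock and light signalling lists also passed higher in arp6. Of 23 clock genes, 11 rose, 9 fell and 3 did not pass. GI rose (2.51, SE 0.18, adjusted p = 1.14e-06) and RVE1 fell (-2.67, SE 0.10, adjusted p = 3.21e-08), in a list that lay higher (median 0.99, camera adjusted p = 0.0125, estimated 0.6). Of 20 light signalling genes, 11 rose, 6 fell and 3 did not pass. The light list (median 0.95, camera adjusted p = 0.0125, estimated 0.6) included falls of HFR1 (-2.29, SE 0.08, adjusted p = 2.55e-08) and HB-2 (-2.16, SE 0.11, adjusted p = 1.71e-07). PIF4 fell (-0.61, SE 0.14, adjusted p = 0.00173), but not with median centring (-0.24, adjusted p = 0.219). The photoreceptor PHYA rose (1.496, SE 0.16, adjusted p = 1.22e-05), but not with the length trend removed (0.07, adjusted p = 0.524). That step also ends the clock, light, SAUR, antenna, glucosinolate and Polycomb calls (adjusted p = 0.317, 0.867, 0.105, 0.289, 0.068 and 0.228) and turns the Polycomb median to -0.10. Quantile normalization ends the clock, light, cold, antenna and flowering calls (adjusted p = 0.361, 0.361, 0.4, 0.262 and 0.0505), and median centring the clock, cold, antenna, flowering and glucosinolate calls (0.0524, 0.0976, 0.0509, 0.0524 and 0.0633). Background subtraction ends the clock, light, cold and glucosinolate calls (adjusted p = 0.239, 0.205, 0.421 and 0.0643), and mean RPKM 10 or more the light, cold, flowering, flavonoid and glucosinolate calls (0.617, 0.361, 0.439, 0.0886 and 0.567). Of 17 warm-response markers, 3 rose, 13 fell and 1 did not pass. They did not pass together (median -0.67, camera adjusted p = 0.16, estimated 0.6), but do, lower, with quantile normalization (-0.86, adjusted p = 0.0144) or a background subtracted (-1.08, adjusted p = 0.03). YUC8 (-1.31, SE 0.10, adjusted p = 1.5e-06) and IAA29 (-1.59, SE 0.13, adjusted p = 2.73e-06) fell and HSP70 rose (0.93, SE 0.21, adjusted p = 0.00186). IAA19 did not pass (-0.09, SE 0.12, adjusted p = 0.477), except higher with median centring or background and length trend removed (0.28 and 0.50, adjusted p = 0.0242 and 0.00149). Of 32 heat shock genes, 9 rose, 19 fell and 4 did not pass. As a list they did not pass (median 0.03, camera adjusted p = 0.565, estimated 0.809). Of 16 SWR1 complex and H2A.Z genes, 6 rose, 5 fell and 5 did not pass. Nor did this list pass (median 0.53, camera adjusted p = 0.198, estimated 0.721). Of 15 Polycomb-silenced developmental regulators, 2 rose, 12 fell and 1 did not pass. These did not pass either (median -0.30, camera adjusted p = 0.198, estimated 0.721). Fry, a test against no change, passes the warm-response, heat shock, SWR1 and Polycomb-silenced lists, all lower (adjusted p = 3.92e-06, 0.00621, 0.00881 and 0.000163), and ends the Polycomb component, light, clock, cold, flavonoid and root calls (0.0922, 0.895, 0.119, 0.17, 0.0922 and 0.0922).

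In all, 25889 genes passed in arp6, 6466 higher and 19423 lower. The split is 9783 and 9094 with quantile normalization, 9854 and 14935 with median centring, 8307 and 9940 with a background subtracted, and 2572 and 3684 at mean RPKM 10 or more. Of the 19423 lower genes, 7397 (38.1 percent) lie under 2 times the WT background of 0.985 RPKM. Change rose with gene length at a rho of 0.473. The 10 highest features hold a mean 8.82 percent of summed RPKM, against 14 percent in WT.

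**Figure D2:**
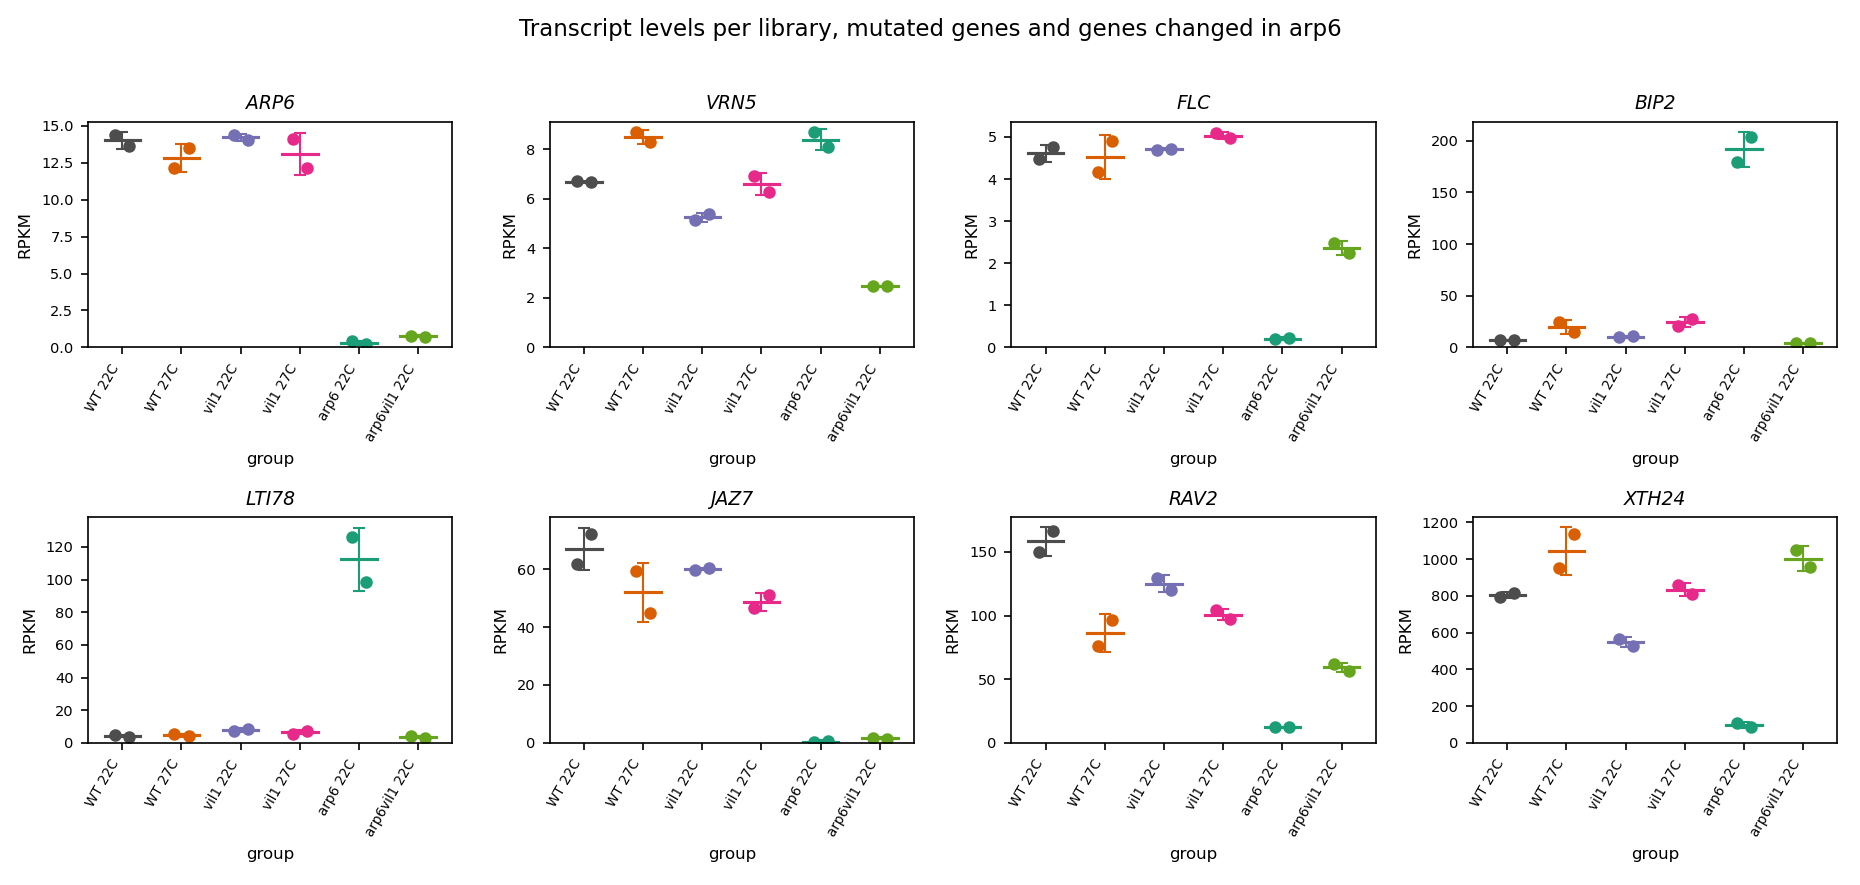
Levels of 8 genes in each library (points, RPKM on a linear axis), with group means (lines) and SDs (bars), 2 libraries per group. ARP6 averages 14 RPKM in WT at 22 °C, 0.303 in arp6 and 0.756 in arp6vil1, and BIP2 7.31, 192 and 4.04.

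The arp6 changes resembled the warm response of WT across genes. Pearson r between the 2 sets of changes was 0.542 over 31454 genes, and 0.367 without WT 27 °C replicate 1. Both contrasts share the WT 22 °C libraries, and simulated groups with no change give 0.499 for that reason. The covariance was 0.181 against 0.0153 simulated, and 0.111 and 0.2 with a different WT 22 °C library in each contrast. For vil1 at 22 °C, r was 0.544 and the covariance 0.057, or 0.0274 and 0.0356 with different WT libraries. For arp6vil1, r was -0.110 and the covariance -0.0227. That r is 0.0182 after quantile normalization, 0.0528 without WT 22 °C replicate 1 and -0.0274 with the length trend removed.

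In arp6vil1 against arp6, genes among the highest in arp6 fell. BIP2 went to 4.04 ± 0.428 RPKM (log2 change -5.26, SE 0.20, adjusted p = 2.3e-08) and SHD to 3.15 ± 0.00194 (-5.30, SE 0.29, adjusted p = 8.7e-08). BIP1 went to 4.93 ± 0.0769 (-5.19, SE 0.21, adjusted p = 2.86e-08) and LTI78 to 3.64 ± 0.548 (-4.60, SE 0.18, adjusted p = 2.54e-08). The jasmonate synthesis enzyme LOX2 fell from 511 ± 42 to 8.06 ± 0.613 (-5.82, SE 0.37, adjusted p = 1.92e-07). So did the sulfur-starvation genes BGLU28 (-6.09, SE 0.55, adjusted p = 2.53e-06) and ATSDI1 (-5.24, SE 0.24, adjusted p = 3.7e-08), with NUDT24 (-5.44, SE 0.38, adjusted p = 4.06e-07) and SHM7 (-4.99, SE 0.33, adjusted p = 2.38e-07). HSP23.6-MITO rose from 1.49 ± 0.739 to 65.1 ± 5.58 (4.76, SE 0.31, adjusted p = 2.37e-07). PHI-1 (3.98, SE 0.19, adjusted p = 3.96e-08), the iron-sulfur assembly gene SUFE2 (3.73, SE 0.11, adjusted p = 8.99e-09) and CRF6 (3.67, SE 0.25, adjusted p = 3.2e-07) rose. The late-embryogenesis gene M17 (4.09, SE 0.39, adjusted p = 4e-06), XTH24 (3.37, SE 0.13, adjusted p = 2.62e-08) and RAV2 (2.17, SE 0.12, adjusted p = 7.92e-08) rose too. FLC went from 0.21 ± 0.032 to 2.36 ± 0.157 (1.47, SE 0.10, adjusted p = 2.35e-07).

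Relative to the all-gene median of 0.12, light signalling (median -1.51, camera adjusted p = 0.000384), salicylic acid defence (-1.29, adjusted p = 0.0018), flavonoid (-1.35, adjusted p = 0.00185) and Polycomb component genes (-1.202, adjusted p = 0.000384) lay lower in arp6vil1 than in arp6. SAUR (0.70, adjusted p = 0.000737) and seed storage genes (1.18, adjusted p = 0.00248) lay higher. Each of the 6 lists has an estimated p of 0.711. Of 20 light signalling genes, 2 rose, 18 fell and 0 did not pass. In that order, counts were 0, 14 and 4 of 18 salicylic acid defence and 1, 17 and 2 of 20 flavonoid genes. They were 3, 19 and 0 of 22 Polycomb component and 16, 0 and 2 of 18 SAUR genes. Of 9 seed storage genes, 9 rose, 0 fell and 0 did not pass. OLEO2 is among the last (2.23, SE 0.14, adjusted p = 1.97e-07). The light call ends at mean RPKM 10 or more (adjusted p = 0.213). Removing the length trend ends the Polycomb and SAUR calls (adjusted p = 0.907 and 0.174). It takes the H3K27 demethylases REF6 from -2.00 to -0.01 and ELF6 from -2.03 to 0.05. PIF4 fell (-0.92, SE 0.14, adjusted p = 0.000119), turning to 0.05 with the length trend removed. HB-2 fell (-0.37, SE 0.11, adjusted p = 0.00957), turning to 0.10 with median centring, a call lost without arp6 replicate 2 (adjusted p = 0.0579). In all, 24881 genes passed, 12917 higher and 11964 lower, 18549 and 8342 with median centring, 15239 and 6593 with the length trend removed, and 4677 and 13963 with a background subtracted.

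Against WT, arp6vil1 plants had higher SUFE2 at 53.4 ± 3.24 RPKM (log2 change 3.40, SE 0.11, adjusted p = 4.74e-08), M17 at 42.8 ± 6.79 (2.61, SE 0.39, adjusted p = 0.000146) and HSP23.6-MITO at 65.1 ± 5.58 (2.47, SE 0.31, adjusted p = 4.5e-05). JAZ7 fell to 1.62 ± 0.256 (-4.70, SE 0.18, adjusted p = 1.29e-07) and ORA47 to 3.76 ± 0.0508 (-4.05, SE 0.11, adjusted p = 1.96e-08). MLP328 fell to 14.1 ± 1.55 (-4.13, SE 0.15, adjusted p = 9.1e-08) and ATSDI1 to 8.98 ± 0.379 (-3.93, SE 0.24, adjusted p = 8.18e-07). Relative to the all-gene median of -0.54, seed storage (median 0.87, camera adjusted p = 6.94e-07), cell-wall (0.41, adjusted p = 0.00275) and glucosinolate genes (0.47, adjusted p = 0.0191) lay higher, and light signalling (-0.55, adjusted p = 0.00207) and Polycomb component genes (-0.49, adjusted p = 0.00275) lower. Each of the 5 lists has an estimated p of 0.46. Of 9 seed storage genes, 2 rose, 0 fell and 7 did not pass. In that order, counts were 6, 8 and 7 of 21 cell-wall and 2, 4 and 8 of 14 glucosinolate genes. Of 20 light signalling genes, 0 rose, 19 fell and 1 did not pass. PIF4 (-1.53, SE 0.14, adjusted p = 4.7e-06), HB-2 (-2.54, SE 0.11, adjusted p = 2.27e-07) and PIL6 (-1.68, SE 0.17, adjusted p = 1.12e-05) are among these. Of 22 Polycomb component genes, 0 rose, 20 fell and 2 did not pass. The H3K27 methyltransferase CLF fell (-1.16, SE 0.10, adjusted p = 5.16e-06). Median centring ends the cell-wall and glucosinolate calls (adjusted p = 0.0633 for both), and removal of the length trend the Polycomb call (adjusted p = 0.114). The glucosinolate call ends at mean RPKM 10 or more too (adjusted p = 0.701), and fry puts it and cell-wall genes lower (0.0723 and 0.0455). In all, 20788 genes passed, 1543 higher and 19245 lower. The split is 7303 and 8137 with quantile normalization, 14258 and 4466 with median centring, and 5292 and 8186 with the length trend removed, so these libraries do not settle which way most genes moved.

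**Figure D3:**
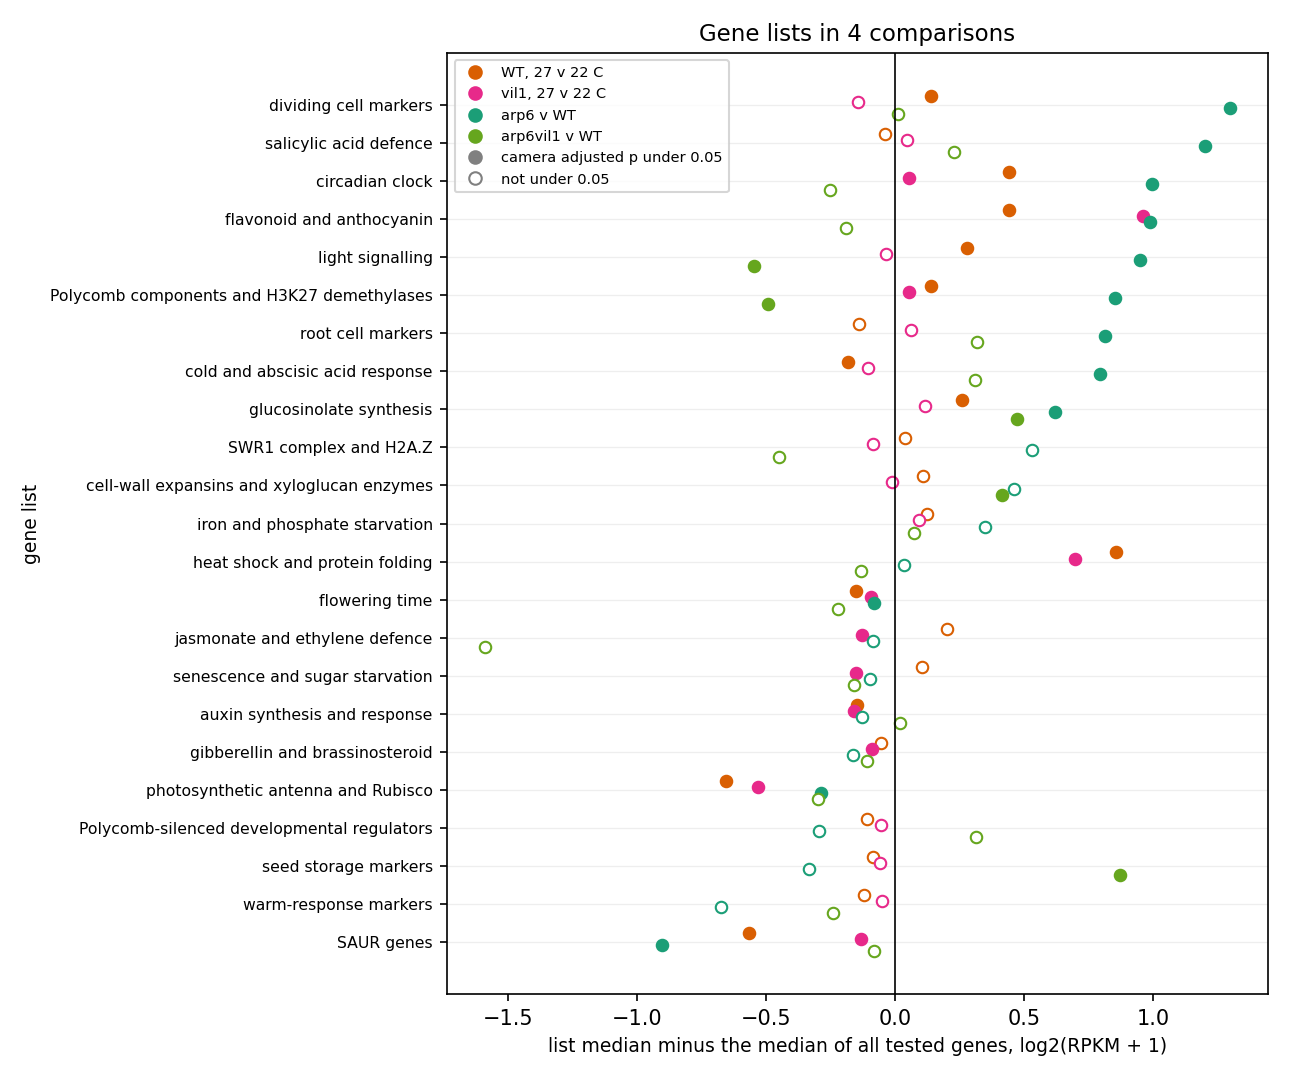
Median log2 change of each gene list minus that of all genes (points) in 4 comparisons of groups of 2 libraries. Filled points passed the camera test at an adjusted p under 0.05, and heat shock genes stand at 0.85 in WT and 0.70 in vil1 at 27 against 22 °C.

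Against vil1, arp6vil1 plants had higher M17 (log2 change 2.68, SE 0.39, adjusted p = 0.000126), PCC1 (2.49, SE 0.38, adjusted p = 0.000176), MRD1 (2.199, SE 0.14, adjusted p = 7.45e-07) and SUFE2 (2.16, SE 0.11, adjusted p = 3.66e-07). The defence gene HSPRO2 (-4.59, SE 0.19, adjusted p = 2.03e-07), JAZ7 (-4.55, SE 0.18, adjusted p = 1.66e-07), MYB73 (-3.95, SE 0.14, adjusted p = 9.16e-08) and SRG3 (-3.88, SE 0.17, adjusted p = 2.12e-07) were lower. Of 20 light signalling genes, 0 rose, 20 fell and 0 did not pass. Relative to the all-gene median of -0.40, they lay lower (median -0.93, camera adjusted p = 5.2e-05, estimated 0.453), with PIF4 (-1.97, SE 0.14, adjusted p = 1.16e-06) and HB-2 (-2.59, SE 0.11, adjusted p = 2.06e-07). Of 23 circadian clock genes, 0 rose, 21 fell and 2 did not pass. The clock list lay lower (median -0.58, camera adjusted p = 0.0152, estimated 0.453), but not with the length trend removed (adjusted p = 0.353), quantile normalization (0.0613), a background subtracted (0.163) or mean RPKM 10 or more (0.104). Of 9 seed storage genes, 6 rose, 0 fell and 3 did not pass. That list lay higher (median 0.98, camera adjusted p = 1.73e-05, estimated 0.453). Camera also passed Polycomb component (-0.47, adjusted p = 0.00359), cell-wall (0.44, adjusted p = 0.00782), root (0.52, adjusted p = 0.0217) and antenna genes (-0.19, adjusted p = 0.0494), none with an estimated correlation (adjusted p = 0.548 for the lowest). Of these, Polycomb and root calls end with the length trend removed (adjusted p = 0.862 and 0.0561), and antenna and root calls with median centring (0.743 and 0.0642). Cell-wall and antenna calls end at mean RPKM 10 or more (adjusted p = 0.0584 and 0.0623), and cell-wall and root calls by fry (0.818 and 0.883). The antenna median turns to 0.13 with a background subtracted (adjusted p = 0.163). In all, 18243 genes passed, 2251 higher and 15992 lower. The split is 8127 and 9035 with quantile normalization, 15345 and 5841 with median centring, and 8747 and 6715 with the length trend removed.

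BIP2 (log2 change -5.70, SE 0.28, adjusted p = 3.47e-07), BIP1 (-5.68, SE 0.30, adjusted p = 3.98e-07), LOX2 (-6.07, SE 0.52, adjusted p = 3.12e-06) and PHS2 (-5.67, SE 0.43, adjusted p = 1.42e-06) showed a lower effect of ARP6 loss in vil1 than in WT plants. PHI-1 had a higher one (4.68, SE 0.26, adjusted p = 4.32e-07). Relative to the all-gene median of 0.30, light signalling (median -2.03, camera adjusted p = 0.000141) and Polycomb component genes (-1.35, adjusted p = 0.000374) lay lower (estimated 0.613 for each). Salicylic acid defence genes (-1.43, adjusted p = 0.00708) lay lower and SAUR genes (0.68, adjusted p = 0.00214) higher (estimated 0.712 for each). The Polycomb and SAUR calls end with the length trend removed (adjusted p = 0.353 and 0.487), at medians of 0.19 and -0.09. Light signalling ends at mean RPKM 10 or more (-1.04, adjusted p = 0.198). PIF4 stood at -1.36 (adjusted p = 0.000112), and at -0.19 (adjusted p = 0.203) with that trend removed. In all, 23648 genes passed, 13362 higher and 10286 lower. The split is 17652 and 8158 with median centring, 14883 and 5556 with the length trend removed, and 4917 and 12478 with a background subtracted.

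Genes higher in arp6 did not keep a rise of that size in arp6vil1. Here 1 arp6 and 1 WT library chose the genes and the others measured them, in all 4 ways. The 2073 to 2639 genes higher in arp6 changed by 1.40 in held-out arp6 and by -0.73 in arp6vil1 against WT, with 12.4 percent moving the same way. The last 2 values are -0.05 and 44.9 percent with quantile normalization, -0.03 and 48.3 percent with the length trend removed, and 0.11 and 57.7 percent with median centring, so the sign depends on scaling. The 2672 to 4135 genes lower in arp6 changed by -1.52 in held-out arp6 and -0.86 in arp6vil1, where the median of all genes was -0.54, with 84.5 percent moving the same way. These are -0.30 and 66.3 percent with quantile normalization, -0.44 and 73.7 percent with the length trend removed, and -0.11 and 55.9 percent with median centring.

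**Figure D4:**
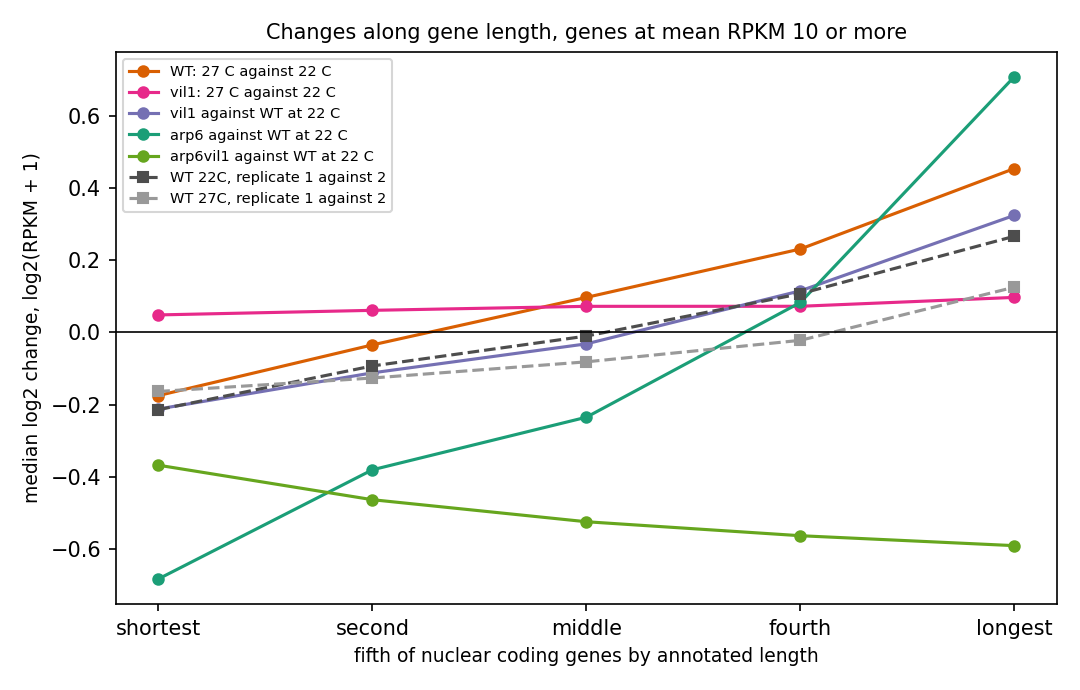
Median log2 change over 5 equal bins of gene length (bp) for 6996 nuclear coding genes at mean RPKM 10 or more, for 5 comparisons (solid) and for replicate 1 against 2 of WT at 22 and 27 °C (dashed). The medians run from -0.17 to 0.45 for WT at 27 against 22 °C and from -0.68 to 0.71 for arp6 against WT.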

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

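Comparisons and lists were fixed before the data were examined, and each test of an explanation below was chosen after the result it bears on was seen. The ARP6 effect, not separable here from library makeup, differed between vil1 and WT plants at 23648 genes. Among the largest differences (log2, vil1 minus WT), LOX2 stands at -6.07, BIP2 at -5.70, BIP1 at -5.68, PHS2 at -5.67 and PHI-1 at 4.68. MIR5642a stands at 6.01 and MIR854d at 4.74, both with values nearly those of another locus. By list, relative to all genes, the ARP6 effect differed by camera at light signalling (-2.03), circadian clock (-1.61), salicylic acid defence (-1.43), Polycomb component (-1.35), flavonoid and anthocyanin (-1.18), seed storage (1.27) and SAUR genes (0.68), none of them with an estimated correlation (adjusted p = 0.613 for light, clock and Polycomb, 0.712 for the others). The clock call also ends with quantile normalization (adjusted p = 0.115). Background subtraction ends the clock and flavonoid calls (0.274 and 0.161), and mean RPKM 10 or more the light, clock and flavonoid calls (0.198, 0.112 and 0.112). Removing the length trend ends the clock, seed storage, SAUR and Polycomb calls (0.282, 0.0619, 0.487 and 0.353) and turns the Polycomb median to 0.19. The response to 27 °C differed by camera at SAUR (0.44), flavonoid and anthocyanin (0.42), cold and abscisic acid response (0.24), photosynthetic antenna and Rubisco (0.22), and root cell marker genes (0.17), higher in vil1. With an estimated correlation these have adjusted p = 0.315 for the first 3, 0.532 for antenna and 0.635 for root genes, and the antenna median turns to -0.13 with quantile normalization. That response also differed at jasmonate and ethylene defence (-0.32), light signalling (-0.29), senescence and sugar starvation (-0.23) and dividing cell marker genes (-0.22), lower in vil1, each with adjusted p = 0.315 with an estimated correlation. Light signalling moves to -0.0442 (adjusted p = 0.356) with the length trend removed, and no list of either direction passes fry for this response.

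Genes called in warm WT plants were mostly higher, the longer ones more so. A bias by gene length between libraries could account for this, because the 2 WT 22 °C libraries, of 1 genotype and temperature, differ along length with a Spearman rho of 0.567. In the shortest of 5 bins of gene length, 25.1 percent of the calls are higher, as such a bias predicts. A difference in depth is excluded, with a ratio of 0.999 between the mean depths of the groups. The direction of most calls is therefore not settled, whereas camera still passes heat-shock, antenna and SAUR genes once the trend is removed, though not with an estimated correlation before it (adjusted p = 0.0943, 0.149 and 0.211), nor antenna genes with quantile normalization (0.619).

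Most genes called in arp6 were lower in RPKM as deposited, but not with quantile normalization (9783 higher and 9094 lower), so the direction itself depends on scaling. For genes near background, reads that reach every other library but not arp6 might account for it: tRNA genes have a median RPKM of 1.31 in the lower of the WT 22 °C libraries and 0 in arp6. At mean RPKM 10 or more such reads are excluded for the 3684 lower calls, which fell by a median of 12.1 RPKM (quartiles 6.84 and 26.2). Which way most calls go at that level still depends on scaling, with 2685 higher and 3600 lower by quantile normalization, and 3719 and 2501 by median centring. The 10 highest features do not take a larger share of arp6 libraries, as they hold 5.2 points less of summed RPKM (-5.2). Summed RPKM is not a share of reads, so a shift of reads toward other or longer genes is not excluded. Whether gene length bias contributes cannot be told: the spread of medians over length is 2.9 times that between WT replicates, and library differences and genotype coincide.

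The arp6 changes resembled the warm response of WT, and those of arp6vil1 did not. A smooth length trend and noise of single WT 22 °C libraries are not the whole source. With that trend removed the covariance is 0.143, with different WT 22 °C libraries at least 0.111, and with both 0.0903 and 0.145. What both libraries share enters each contrast and is not excluded. Removing the length trend did not bring out a resemblance in arp6vil1, where r is then -0.0274. A biological effect of VIL1 on the arp6 transcriptome and some other difference between the arp6vil1 and remaining libraries, such as their ribosomal and chloroplast RNA, could each give this pattern, and with genotype and library makeup coinciding no test here separates them.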

How the results depend on the processing

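Of 246 gene calls named for a contrast, 194 kept their direction and side of the threshold under every alternative, 40 were lost without some library and 34 under another alternative. Of 83 list calls, 2 kept theirs throughout, heat shock genes in warm vil1 and cold and abscisic acid response genes in vil1 against WT at 27 °C, 28 were lost without some library and 81 under another alternative. The settings chosen after seeing the data, given above, include median centring for held-out genes and likeness. Where no cause is named, the cause was not tested. Warm WT and warm vil1 mean 27 against 22 °C, and the 27 °C and ARP6 differences those of the 27 °C response and the ARP6 effect, vil1 minus WT. Values in arp6, and in vil1 at 22 or 27 °C, are against WT at that temperature.

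Counts of genes that passed moved by more than 1.5 times as follows. Higher minimum levels test fewer genes and a minimum change keeps fewer calls by construction. With a pseudocount of 5: 1 in the 27 °C difference. With mean RPKM of 5 or more: 2450 in vil1 at 22 °C, 10843 in arp6, 11279 in arp6vil1 against arp6, 10970 in arp6vil1 against WT, 11076 in arp6vil1 against vil1 and 10818 in the ARP6 difference. With no variance trend: 537 in vil1 at 22 °C. With only the groups of the contrast fitted: 1290 in warm WT, 2088 in warm vil1, 57 in vil1 at 22 °C and 120 in vil1 at 27 °C. With a minimum absolute log2 change of 1: 422 in warm WT, 137 in warm vil1, 140 in vil1 at 22 °C, 92 in vil1 at 27 °C, 12490 in arp6, 10323 in arp6vil1 against arp6, 7123 in arp6vil1 against WT, 6828 in arp6vil1 against vil1 and 14490 in the ARP6 difference. With mean RPKM of 10 or more: 3580 in warm WT, 1963 in vil1 at 22 °C, 6256 in arp6, 6580 in arp6vil1 against arp6, 5888 in arp6vil1 against WT, 6168 in arp6vil1 against vil1 and 6379 in the ARP6 difference. With the length trend removed: 4115 in warm WT, 1 in the 27 °C difference, 4028 in vil1 at 22 °C, 492 in vil1 at 27 °C and 13478 in arp6vil1 against WT. With that trend removed at mean RPKM of 10 or more: 3483 in warm WT, 1133 in warm vil1, 3 in the 27 °C difference, 1999 in vil1 at 22 °C, 6003 in arp6, 6298 in arp6vil1 against arp6, 5095 in arp6vil1 against WT, 5589 in arp6vil1 against vil1 and 6102 in the ARP6 difference. With background subtracted and the length trend removed: 1149 in warm vil1, 6 in the 27 °C difference, 3268 in vil1 at 22 °C, 566 in vil1 at 27 °C, 16201 in arp6, 15802 in arp6vil1 against arp6 and 14647 in the ARP6 difference. With nuclear protein-coding genes alone: 9 in the 27 °C difference and 2639 in vil1 at 22 °C. With WT and vil1 libraries alone: 437 in warm vil1, 156 in vil1 at 22 °C and 161 in vil1 at 27 °C. With WT and vil1 libraries alone and the length trend removed: 2610 in warm WT and 406 in vil1 at 22 °C. With voom on recovered reads: 7 in the 27 °C difference, 2717 in vil1 at 22 °C and 477 in vil1 at 27 °C.

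Across single libraries left out, the lowest and highest values were -0.0181 to 0.0577 for ARP6 in vil1 at 22 °C, -0.0757 to 0.13 for ARP6 in vil1 at 27 °C, -0.12 to 0.0719 for FLC in warm WT, -0.0829 to 0.19 for HB-2 in vil1 at 22 °C and -0.23 to 0.0396 for IAA19 in arp6. They were -0.0313 to 0.065 for IAA19 in warm vil1, -0.20 to 0.29 for PIF4 in warm WT, 2047 to 6847 in warm WT, 0.367 to 0.645 for likeness of arp6 and -0.134 to 0.0528 for likeness of arp6vil1, and 0 to 1803 in the 27 °C difference, 30 to 8939 in vil1 at 22 °C, 62 to 460 in vil1 at 27 °C, 0.413 to 0.733 for likeness of vil1 and 149 to 1271 in warm vil1.

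Nothing in the labels says that replicate numbers pair the libraries, and deviations of same-numbered libraries from their group means correlate at -0.249 to 0.22 over 15 pairs of groups. The highest is between WT at 22 and 27 °C, where depths agree by number and replicate 1 against 2 changes with gene length in both groups (rho 0.567 and 0.447). Fitting the number as a block gives 5704 calls in warm WT and 619 in vil1 at 22 °C.

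Held-out medians (log2) and likeness to the WT warm response (Pearson r) moved as follows. With a minimum log2 change of 0.58 for choosing genes: -0.25 for warm-suppressed genes in vil1. With genes chosen by the fit of all libraries: -0.19 for warm-suppressed genes in vil1, 0.20 for warm-induced genes in vil1 and -0.50 for genes lower in arp6. With a pseudocount of 0.1: -0.94 for genes higher in arp6 and -0.0451 for likeness of arp6vil1. With quantile normalization: -0.0485 for genes higher in arp6, -0.30 for genes lower in arp6 and 0.0182 for likeness of arp6vil1. With the length trend removed: -0.0271 for genes higher in arp6, -0.44 for genes lower in arp6 and -0.0274 for likeness of arp6vil1. With median centring: 0.11 for genes higher in arp6 and -0.11 for genes lower in arp6. With mean RPKM of 10 or more: -0.60 for genes higher in arp6, -0.54 for genes lower in arp6 and -0.164 for likeness of arp6vil1. With that trend removed at mean RPKM of 10 or more: -0.0345 for genes higher in arp6, -0.27 for genes lower in arp6 and 0.444 for likeness of vil1. With an RPKM minimum of 1 for choosing genes: -0.53 for genes lower in arp6. With nuclear protein-coding genes alone: -0.172 for likeness of arp6vil1.

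The test of a list changed direction in these cases, given with the median relative to all genes and the adjusted p in brackets, which for fry tests a list against no change, not against other genes. With fry: warm-response markers -0.12 in warm WT (0.752), heat shock 0.035 in arp6 (0.00621), SWR1 and H2A.Z 0.53 in arp6 (0.00881), cell-wall 0.41 in arp6vil1 against WT (0.0455), glucosinolate 0.47 in arp6vil1 against WT (0.0723) and root cell markers 0.52 in arp6vil1 against vil1 (0.883). With the length trend removed: Polycomb components -0.24 in warm WT (0.0809), circadian clock -0.0319 in vil1 at 22 °C (0.915), Polycomb components -0.0984 in arp6 (0.228), SWR1 and H2A.Z -0.32 in arp6 (0.354), Polycomb components -0.0748 in arp6vil1 against arp6 (0.907), Polycomb components 0.0114 in arp6vil1 against vil1 (0.862) and Polycomb components 0.19 in the ARP6 difference (0.353). With mean RPKM of 10 or more: warm-response markers -0.0438 in warm WT (0.856) and light signalling -0.0911 in arp6 (0.617). With quantile normalization: antenna -0.13 in the 27 °C difference (0.27), antenna -0.0936 in vil1 at 27 °C (0.318), heat shock -0.0678 in arp6 (0.79) and Polycomb-silenced 0.18 in arp6 (0.361). The median changed sign while the test did not for SAUR genes in the ARP6 difference (-0.0926 with the length trend removed), antenna genes in arp6vil1 against vil1 (0.13 with background subtracted), and jasmonate and clock genes in warm vil1 without 27 °C replicate 1 and 2 (0.0313 and -0.0102). Heat shock genes, at medians near 0, did so in arp6 and in the 27 °C difference under several alternatives.

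Named genes changed sign, most of them at values near 0, in these cases. With quantile normalization: PIF4 -0.0446 in warm WT, YUC8 -0.00185 in warm vil1, IAA19 -0.13 in warm vil1, FLC -0.0689 in warm vil1, IAA19 0.23 in arp6, HB-2 0.11 in arp6vil1 against arp6, FLC 0.12 in arp6vil1 against WT and HB-2 0.0477 in the ARP6 difference. With median centring: PIF4 -0.14 in warm WT, YUC8 -0.00368 in warm vil1, IAA19 -0.13 in warm vil1, FLC -0.071 in warm vil1, IAA19 0.28 in arp6, HB-2 0.0988 in arp6vil1 against arp6 and FLC 0.11 in arp6vil1 against WT. With the length trend removed: PIF4 -0.28 in warm WT, IAA19 -0.0636 in warm vil1, FLC -0.0499 in warm vil1, IAA19 0.24 in arp6, ELF6 0.046 in arp6vil1 against arp6, PIF4 0.0514 in arp6vil1 against arp6 and REF6 0.51 in the ARP6 difference. With that trend removed at mean RPKM of 10 or more: PIF4 -0.28 in warm WT and PIF4 0.0514 in arp6vil1 against arp6. With background subtracted and the length trend removed: PIF4 -0.30 in warm WT, IAA19 -0.0898 in warm vil1, FLC -0.0622 in warm vil1, IAA19 0.50 in arp6 and PIF4 0.0592 in arp6vil1 against arp6. With WT and vil1 libraries alone and the length trend removed: PIF4 -0.28 in warm WT, IAA19 -0.0636 in warm vil1 and FLC -0.0499 in warm vil1. With background subtracted: IAA19 -0.0125 in warm vil1 and IAA19 0.22 in arp6.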

Other observations

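3 genes changed in vil1 plants at both temperatures without a similar level in arp6vil1, and were singled out after their values were seen. QQS had 17.5 and 17.7 RPKM in vil1 at 22 and 27 °C, 1.35 and 1.35 in WT, and 2.48 ± 0.154 in arp6vil1. The neighbouring genes MRD1 and HEI10 had 6.57 and 3.58 RPKM in vil1 at 22 °C, 34 and 15.6 in WT, and 33.7 ± 1.81 and 14.5 ± 0.828 in arp6vil1.

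PCC1 had 224 ± 25.3 RPKM in arp6 and 45.9 ± 7.21 in arp6vil1, against 18.5 ± 10.6 in WT and 7.47 ± 2.56 in vil1 at 22 °C. At 22 °C, LSU1, which responds to sulfur supply, had 423 ± 67.3 RPKM in WT, 141 ± 4.5 in vil1, 497 ± 69.5 in arp6 and 48.7 ± 5.64 in arp6vil1. ATSDI1 had 153 ± 31.8, 88.3 ± 0.984, 378 ± 35.5 and 8.98 ± 0.379.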
